A study of Mus musculus with 40 samples.

How the data were processed

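Bulk RNA sequencing was read out in 2 blood-forming cell populations sorted from C57BL/6 mice: LSK cells (lineage-negative, Sca-1-positive, Kit-positive, the fraction that holds hematopoietic stem cells and early multipotent progenitors) and MEP (megakaryocyte-erythroid progenitors, the precursors of platelets and red cells). Mice were wild type (WT), carried Jak2 V617F (JVF, the activating kinase mutation found in myeloproliferative neoplasms), or carried Jak2 V617F with an altered Trp53 gene: loss of 1 copy (p53+/-) or both copies (p53-/-), or the R172H missense allele with a normal copy (p53R172H/+) or with no second copy (p53R172H/-). A further pair of MEP groups, p53-/- and p53R172H/-, is marked AML in the sample titles and is called leukemic here.

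Per the labels' protocols, 1.9 to 2 ng of total RNA per sorted sample was amplified with SMART-Seq v4, an oligo-dT primed full-length cDNA method that carries no molecular identifiers and does not mark strand, and libraries were made with KAPA Hyper Prep. Whole-number counts per gene were deposited by the authors as raw, unnormalised values, in 3 tables of 33924 gene symbols each: 16 LSK libraries, 18 MEP libraries and 6 leukemic MEP libraries. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1, DESeq2 and the mm9 genome build were named, with no role or order, and the gene annotation, strand setting and read filters are not given in the sources used here. Gene symbols are printed as the tables give them, and no genome positions are given because the reference annotation used here is of another build. That annotation, GENCODE M21, served only for GC content, transcript length and chromosome of genes matched by symbol, which 96.3% of the tested genes had. Reads of genes with near-identical copies, such as the alpha- and beta-globin genes, the major histocompatibility genes, ribosomal protein genes and Pcna-ps2, can be split between copies by the counting, so their single values are uncertain.

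All 40 libraries were mapped to 14 groups by title and genotype. Every group had 3 libraries except LSK p53+/- and LSK p53R172H/-, which had 2. Nothing in the labels says that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise by a chi-square test of their counts, and none was merged.

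A conflict in the labels concerns the p53-/- MEP. The descriptions of the samples titled leukemic p53-/- name the leukemic table but give column names that stand in the MEP table. The descriptions of the p53-/- samples not titled leukemic name the MEP table but give column names that it does not hold. Libraries were assigned by the table that the description names, and each comparison with p53-/- MEP was also computed with the libraries assigned by column name. The 2 sets are called the p53-/- libraries of the MEP table and the p53-/- libraries of the leukemic table, and no assignment was inferred from expression.

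A second limit is a possible batch, known only from a column name prefix. Every p53R172H library, in both cell populations and in the leukemic pair, has a column name that starts with the same prefix (14 libraries), and no other library has it (26 libraries). Comparisons of a p53R172H group with a group of another genotype therefore cannot be told apart from such a batch. Comparisons between 2 p53R172H groups, or between 2 groups without the allele, share the prefix or its absence, which does not show that they share a batch.

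Genes were kept with filterByExpr (minimum count 10, minimum total 15). Library sizes were scaled by TMM, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. One fit was made for the 18 MEP libraries (15437 genes), 1 for the 16 LSK libraries (16817 genes), 1 for the 6 leukemic libraries (12897 genes), and 1 each over joined tables for leukemic against other MEP (14701 genes) and for LSK against MEP (17928 genes). The joined fits use raw counts, and the table cannot be told apart there from the cell population or the leukemic label. The word rose or fell is used of genes past this threshold. Log2 changes are given ± the standard error, and group levels as mean ± SD in CPM (counts scaled to the library total) with the number of libraries. Where every library of 1 group had 0 counts, a fold is given as a lower bound against a floor of 3 counts in each library. Floors cover counting error only.

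The comparisons, 33 gene lists and the rule for naming genes were fixed before the data were examined. Genes were named by 3 routes: 21 genes tied to the study's question, among them Trp53, Cdkn1a, Bmp2, Bmp4, Smad1, Id1, Klf1, Gata1 and Mpo; the genes with the largest changes in each direction among those past the threshold with mean log2 CPM of at least 3 and no overlap between the libraries compared; and up to 4 members with the smallest p of each list past its test. Sex-linked genes were left out of the second route. Lists with at least 5 tested members were tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Every list is also given with the count of members called when p-values are adjusted over the list alone, and with the test repeated at a correlation estimated from the list, which is stricter.

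On counts simulated for the real genes and libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among genes with a mean log2 CPM above 3, the same steps recovered 86.4% of 4-fold, 20.9% of 2-fold and 1.49% of 1.5-fold changes in MEP p53R172H/- against JVF, and 98.5%, 68.7% and 10.4% in LSK p53R172H/- against JVF. In the leukemic pair the shares were 68.2%, 7.46% and 1.49%. Changes of 1.5-fold were therefore mostly missed in the simulation. Far fewer genes were changed there than were called in the real data (8078 of 15437 in MEP p53R172H/- against JVF), which makes the adjusted threshold stricter. The shares therefore do not carry over to the real comparisons, nor to groups of smaller spread.

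Alternatives fixed in advance were DESeq2 1.42.0 in place of edgeR, median-ratio size factors in place of TMM, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were the assignment by column name, WT as the control, the comparisons within libraries with or without the column name prefix, the same comparisons fitted without the other libraries, the fit without the p53-/- libraries, the removal of a curve of GC content and transcript length from each library, and the removal of the JVF MEP libraries with a steep GC trend.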

Results

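Gene expression was measured in 40 libraries from sorted mouse LSK and MEP cells, which span the path from blood stem cells to red cell and platelet precursors. The LSK set had 16 libraries: 3 each from WT, JVF, p53-/- and p53R172H/+ animals, and 2 each from p53+/- and p53R172H/- animals, all Trp53-altered groups also carrying Jak2 V617F. The MEP set had the same 6 genotypes with 3 libraries each, and 6 further MEP libraries carried a leukemic label, 3 p53-/- and 3 p53R172H/-. Counted reads per library ran from 14.9 to 57.1 in units of 1e6, with both ends of the range in p53R172H/- groups. Counts in brackets after a list count are those adjusted over the list alone, and an adjusted p in the same brackets is that of camera with an estimated correlation. The comparisons ask what Jak2 V617F changes in each population, what each Trp53 alteration adds, and what sets leukemic cells apart, with the BMP2/SMAD pathway as the study's focus.

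Trp53, the gene for the tumor suppressor p53, was read first as a check of the labels. In LSK it stood at 404 ± 31.2 CPM in WT (mean ± SD, n = 3), 349 ± 45.9 in JVF (n = 3) and 80.9 ± 17.4 in p53-/- (n = 3). In MEP it stood at 960 ± 137 CPM in WT, 300 ± 120 in JVF and 22.6 ± 2.62 in the p53-/- libraries of the MEP table (n = 3 each). It stood at 51.1 ± 19.8 in the p53-/- libraries of the leukemic table (n = 3). The libraries labelled p53+/- did not have less Trp53 than JVF, with 396 ± 16.1 CPM in LSK (n = 2) and 494 ± 189 in MEP (n = 3). Against WT the MEP mean was lower, with a log2 change of -1.02. In the p53R172H groups total Trp53, which gene counts do not split by allele, was at 471 ± 22.1 CPM in LSK p53R172H/+ (n = 3) and 305 ± 58.5 in LSK p53R172H/- (n = 2). It stood at 343 ± 7.58 CPM in MEP p53R172H/+, 194 ± 18.2 in MEP p53R172H/- and 207 ± 42.7 in leukemic p53R172H/- (n = 3 each).

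**Figure D1:**
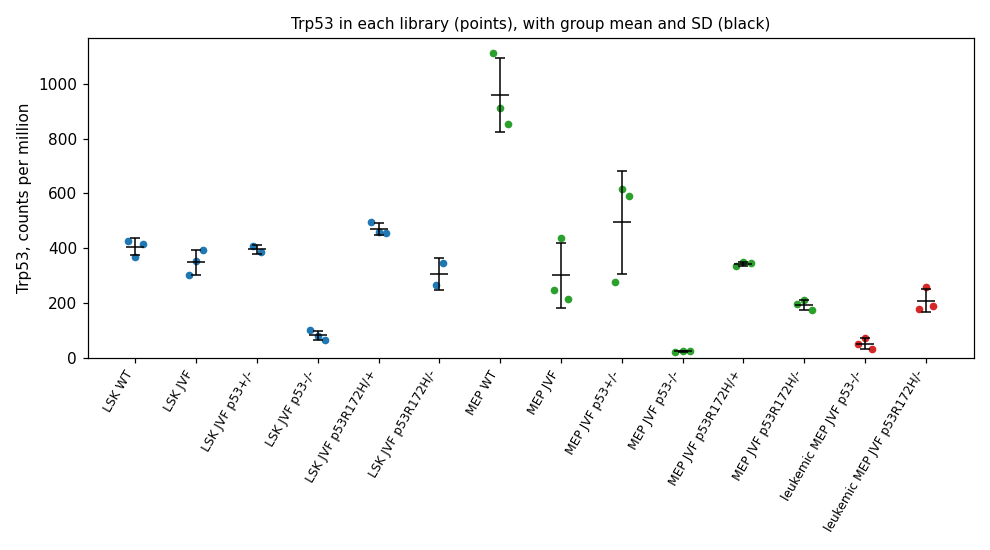
Trp53 in counts per library scaled to CPM (vertical axis) in the 14 groups, with points for libraries (blue LSK, green MEP, red leukemic MEP) and black marks for mean and SD. The p53-/- groups lie lowest, at means of 80.9 CPM in LSK, 22.6 in MEP (libraries of the MEP table) and 51.1 in leukemic MEP (libraries of the leukemic table). The p53+/- groups lie at 396 and 494 CPM.

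The WT libraries showed how the populations differ before any mutation. Trp53 itself was lower in LSK than in MEP (log2 change -1.70 ± 0.26). Of 29 erythroid maturation genes, 22 were lower in LSK and 2 higher, the same counts when adjusted over the list alone (adjusted p = 0.0537 with an estimated correlation in camera), among them Rhag, part of the Rh antigen complex (-5.24 ± 0.34), Tfrc, the transferrin receptor that imports iron (-4.71 ± 0.31), and Gata1, the master regulator of red cell genes (-3.78 ± 0.25). Stem cell genes ran the other way, with 21 of 26 higher and 1 lower in LSK (22 and 1 adjusted over the list alone, adjusted p = 0.0964). They included Hlf (5.92 ± 0.53), Cdkn1c, a cell cycle inhibitor that holds stem cells quiescent (7.82 ± 0.79), and Ly6a, which encodes the Sca-1 antigen of the sort itself (7.41 ± 0.79). BMP pathway components were also an LSK feature: 16 of 27 were higher and 0 lower (16 adjusted over the list alone). They were led by the signal transducers Smad4 (2.31 ± 0.22) and Smad1 (4.85 ± 0.47), the decoy receptor Bambi (5.24 ± 0.50) and the inhibitor Smad6 (5.36 ± 0.56). Among 10 BMP target genes 6 were higher (6 adjusted over the list alone, adjusted p = 0.0783), among them Runx2 (4.74 ± 0.59) and Smad7. Id1, which is induced by BMP signals, was higher by 3.80 ± 0.59.

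Granulocyte-monocyte progenitor genes were higher in LSK for 14 of 16 members (15, and 1 lower, adjusted over the list alone), such as Sfpi1, which encodes the myeloid factor PU.1 (5.67 ± 0.39), and Cebpa (8.38 ± 0.70). MEP had the machinery of dividing cells: 21 of 25 mitosis genes (22 adjusted over the list alone; Kif20a -2.49 ± 0.22, Ttk -2.85 ± 0.26) and 14 of 16 homologous recombination genes (14; Fanci -3.65 ± 0.33) were lower in LSK. So were 23 of 27 ribosome biogenesis genes (24; Nolc1 -2.46 ± 0.20) and 19 of 28 DNA replication genes (21, adjusted p = 0.0917; Mcm10 -3.07 ± 0.21). In the camera tests the LSK-MEP difference held with an estimated correlation for BMP components (adjusted p = 0.0301), granulocyte-monocyte genes (0.0301), mitosis (0.0301), ribosome biogenesis (0.0149) and homologous recombination (0.0391). It was lost for erythroid genes, stem cell genes, DNA replication and BMP targets. In edgeR 9251 of 17928 genes differed, 4977 higher and 4274 lower, and the median gene lay 0.174 above 0. The 2 populations come from separate tables.

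In LSK, red cell genes were higher and early response genes lower in JVF than in WT. Trp53 did not change (-0.12 ± 0.15, edgeR adjusted p = 0.698). Of 29 erythroid maturation genes 9 rose and 0 fell (17 rose adjusted over the list alone, adjusted p = 0.0988), led by the globins Hbb-b1 (3.64 ± 0.42), Hbb-b2 (2.64 ± 0.34) and Hba-a1 (2.58 ± 0.37) and by Tfrc (2.12 ± 0.28). Heme synthesis genes followed with 6 of 17 (8 adjusted over the list alone, adjusted p = 0.0988), including Fech, which inserts iron (0.78 ± 0.14), Hmbs (0.88 ± 0.17) and Alas2, the red cell form of the first enzyme (3.25 ± 0.64). Klf1, the erythroid Krueppel-like factor, rose by 1.61 ± 0.34. Hbb-b1 stood at 257 ± 141 CPM in JVF and 22.1 ± 1.95 in WT. Among macrophage genes 9 of 16 rose (11 adjusted over the list alone, adjusted p = 0.0988), namely the complement genes C1qb (4.31 ± 0.86), C1qc (4.16 ± 0.90) and C1qa (3.90 ± 0.92). The red pulp macrophage factor Spic (2.26 ± 0.47) and the adhesion molecule Vcam1 (3.81 ± 0.88) rose with them, as did Clec4n (10.0 ± 1.19) and Fcna (4.60 ± 0.99) outside the list. Which cells in the sorted fraction hold the red cell and macrophage RNA was not tested. Dividing cell genes rose as well: 14 of 25 mitosis genes (19 adjusted over the list alone, adjusted p = 0.0048; Ccnb1 1.14 ± 0.11, Nusap1 0.61 ± 0.10) and 6 of 28 DNA replication genes (8, adjusted p = 0.0988; Tk1 0.60 ± 0.11). So did 16 of 26 oxidative phosphorylation genes (24, adjusted p = 0.0808; Ndufv1 0.65 ± 0.11).

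Immediate early genes, which respond within minutes to growth factors and to handling of cells, fell for 11 of 19 members (13 adjusted over the list alone, adjusted p = 0.00125): Fos by -5.13 ± 0.62, Hspa1b by -3.59 ± 0.34, Jun by -3.27 ± 0.42, Egr1 by -2.70 ± 0.39 and Zfp36 by -2.28 ± 0.19. Stem cell genes fell for 4 of 26 (12 adjusted over the list alone, adjusted p = 0.114), Ndn by -2.33 ± 0.49 and Slamf1, a stem cell surface marker, by -1.20 ± 0.31. Lymphoid priming genes fell for 4 of 14 (5, adjusted p = 0.0751), Dntt by -1.21 ± 0.17 and Satb1 by -0.64 ± 0.12. Of the BMP genes, Smad1 fell by -0.53 ± 0.12 as the 1 of 27 components past the threshold (adjusted p = 0.146 with an estimated correlation in camera), while Id1 (1.82 ± 0.32) and Id2 (1.46 ± 0.26) rose. With an estimated correlation camera kept the mitosis and immediate early lists, and lost the others that are named. In edgeR 718 of 16817 genes changed, 437 higher and 281 lower. DESeq2 gave 1594, and leaving out single libraries moved the count to 274 (without JVF 1), 250 (JVF 3), 398 (WT 1), 185 (WT 2) and 179 (WT 3).

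Loss of both Trp53 copies in Jak2-mutant LSK touched few genes. Trp53 fell by -2.10 ± 0.15, and p53 targets fell for 2 of 30 members (4 adjusted over the list alone, adjusted p = 0.0747): Phlda3, a repressor of Akt (-1.82 ± 0.21), and Ei24 (-0.61 ± 0.13). The classic targets Cdkn1a (-0.60 ± 0.21, edgeR adjusted p = 0.23), Mdm2 (-0.15 ± 0.24, edgeR adjusted p = 0.877) and Ccng1 (-0.65 ± 0.15, edgeR adjusted p = 0.0634) did not pass. The other large falls were Pcna-ps2 (-2.89 ± 0.20), Cuedc1 (-1.98 ± 0.13), Mtmr9 (-1.83 ± 0.15) and Cd86, a T cell costimulator (-1.81 ± 0.34). The largest rises were Cebpb, a myeloid stress factor (2.94 ± 0.49), Ano8 (2.12 ± 0.43), Tifab (2.07 ± 0.37) and Eid2 (2.05 ± 0.42). Lymphoid Satb1 rose by 0.57 ± 0.12. With WT as the control Pcna-ps2 (0.0868), Cd86 (0.295) and Satb1 (-0.0698) were not called and had the opposite sign.

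Type II interferon genes leaned upward in the same comparison, with 0 of 20 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 7.05e-05, adjusted p = 0.449 with an estimated correlation). The fall of p53 targets was likewise past camera at the preset correlation (adjusted p = 0.00378) and not with the estimated one. The lymphoid list had a median of 0.144 and a mean of -0.172, and the granulocyte-monocyte list 0.267 and -0.19, while camera put both upward (adjusted p = 0.533 and 0.653 with an estimated correlation). In edgeR 145 of 16817 genes changed, 102 higher and 43 lower. DESeq2 gave 554 (320 higher, 234 lower), the fit of only these groups 77, no low-count filter 288, WT as control 456 and the removal of GC and length curves 233. The count was 51 without p53-/- 1, 54 without JVF 2 and 67 without JVF 3.

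In LSK labelled p53+/-, where Trp53 was not lower (0.12 ± 0.16, edgeR adjusted p = 0.767), proliferation genes ran below JVF. Mitosis genes fell for 4 of 25 (14 adjusted over the list alone, adjusted p = 0.0561): Nusap1 (-0.77 ± 0.12), Ccnb1 (-0.66 ± 0.13), the cyclin-dependent kinase Cdk1 (-0.68 ± 0.13) and Birc5 (-0.63 ± 0.14). DNA replication genes fell for 2 of 28 (9 adjusted over the list alone, adjusted p = 0.371; Tyms -0.72 ± 0.13), and the repair genes Brca2 (-0.79 ± 0.16) and Chek1 (-0.76 ± 0.16) for 2 of 16 (3, adjusted p = 0.454). Runx1, a regulator of definitive blood formation, rose by 0.88 ± 0.13, the chemokine receptor Ccr2 by 3.91 ± 0.46 and the cholesterol enzyme Lss by 1.66 ± 0.25. In turn Pcna-ps2 (-3.29 ± 0.25), Hspa1b (-2.56 ± 0.41) and Hddc3 (-2.19 ± 0.18) fell. No list held in camera with an estimated correlation.

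The edgeR count was 214 of 16817 genes, 145 higher and 69 lower. DESeq2 gave 1454 (555 higher, 899 lower), median-ratio factors 194 with 97 on each side, no filter 389, only these groups 532, WT as control 88 and the GC and length curves 138. With WT as the control Ccnb1 (0.477) and Birc5 (0.0206) turned direction. The p53+/- libraries had Ddx3y, a Y chromosome gene, at 27.5 ± 6.9 CPM (n = 2) and JVF at 0 (n = 3), so sex differs too. Without single libraries the count was 11 (p53+/- 1), 18 (p53+/- 2), 20 (JVF 1) and 61 (JVF 2).

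The p53R172H groups were compared first with each other, since these libraries share a column name prefix. In MEP, loss of the remaining normal copy was read from 6 libraries fitted on their own. Trp53 fell by -0.77 ± 0.07. Interferon genes rose together: 13 of 28 type I members (17 adjusted over the list alone, adjusted p = 0.0496), such as Usp18 (1.43), Rtp4 (1.49), the transcription factor Stat1 (1.05) and Oasl1 (1.13). So did 8 of 19 type II members (14, with 2 lower, adjusted over the list alone, adjusted p = 0.208), such as the class I light chain B2m (0.53), the immunoproteasome subunit Psmb9 (0.83) and Gbp3 (2.12). Myeloid genes fell: 6 of 14 granulocyte-monocyte genes (7 adjusted over the list alone, adjusted p = 0.0953), among them the granule proteins Mpo (-1.73), Elane (-1.83) and Ctsg (-1.72). Mast and basophil genes fell for 6 of 11 (8, adjusted p = 0.0496), among them Hdc, which makes histamine (-1.95), Fcer1a (-1.86) and Cpa3 (-1.18). Ribosome biogenesis genes rose for 8 of 27 (15 adjusted over the list alone, adjusted p = 0.0496; Ncl 0.32, Nop2 0.38) and DNA replication genes for 7 of 28 (9, with 1 lower, adjusted p = 0.405; Rrm1 0.25, Mcm2 0.28). By contrast, 6 of 29 erythroid genes fell and 2 rose (13 and 4, adjusted p = 0.182), with Kel at -0.84 and Slc4a1 at -1.32. Heme genes fell for 5 of 17 (7, adjusted p = 0.26), with Alas2 at -0.89.

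Klf1 (0.06, edgeR adjusted p = 0.426), Gata1 (0.15, edgeR adjusted p = 0.112) and Cdkn1a (-0.13, edgeR adjusted p = 0.816) did not change there, and mean Mpo was 20.1 ± 1.3 CPM in p53R172H/- against 69.7 ± 4.55 in p53R172H/+. With an estimated correlation camera kept type I interferon, mast cell and ribosome biogenesis genes and lost the other lists. From p53+/- to p53-/- MEP, fitted alone with the libraries of the MEP table, these 3 lists went the other way. Type I interferon genes fell for 11 of 27, with 2 higher (11 and 2, adjusted p = 0.674; Usp18 -5.05), mast cell genes rose for 7 of 12 (7, adjusted p = 0.513; Hdc 6.28) and ribosome biogenesis genes fell for 18 of 27 (18, adjusted p = 0.513). DNA replication genes also fell there, for 24 of 28, with 1 higher (24 and 2, adjusted p = 0.513). With the p53-/- libraries of the leukemic table instead, single genes were mixed, by group means of TMM-scaled CPM from separate fits. Against p53+/-, Hdc (0.558 against 4.07), Bop1 (175 against 405) and Tk1 (233 against 299) were lower. Prss34 (3.98 against 0.224), Srm (662 against 297) and Ccne1 (224 against 113) were higher. The opposite directions of the lists are shown for the reading by table only. For p53R172H/- against p53R172H/+ MEP the count was 1107 of 13098 genes, 476 higher and 631 lower, with these 6 libraries fitted alone. That choice was made after the pooled fit had called 7. The spread of these groups was smaller than in the other MEP groups. The biological coefficient of variation was 0.0873 in p53R172H/+ and 0.147 in p53R172H/- against 0.419 in MEP JVF, and the pooled fit shares 1 estimate. Separate mice are not stated in the labels, so the 1107 calls may rest on a technical spread. In that pooled fit type I interferon (adjusted p = 0.0369), granulocyte-monocyte (0.00857) and mast cell (0.00857) lists held in camera with an estimated correlation.

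In LSK the same step from p53R172H/+ to p53R172H/-, with 3 and 2 libraries, changed 14 of 14979 genes when fitted alone, 1 higher and 13 lower, and 529 in the pooled fit. Trp53 was at -0.60 (edgeR adjusted p = 0.126), and Fn3krp, a repair enzyme for glycated proteins (-4.79), Cuedc1 (-1.63) and Sox6, a partner of globin gene control (-1.32), fell. Fn3krp fell in MEP as well (-5.04). Sox6 and Fn3krp were chosen after their values were seen.

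Over all genotypes, LSK with both Trp53 copies altered was compared with LSK with 1 altered copy. Trp53 fell by -1.36 ± 0.12, and of 30 p53 targets 2 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.178), with Ccng1 at -0.60 ± 0.12 and the death gene Bbc3 at -0.92 ± 0.19. Ribosomal protein genes rose for 26 of 27 (27 adjusted over the list alone, adjusted p = 0.178; Rps8 0.61 ± 0.10). Short genes also lay higher in LSK p53-/- (0.532 log2 units from the mean of all libraries) than in LSK p53+/- (0.303). They likewise lay higher in LSK p53R172H/- (-0.251, with single libraries at -0.511 and 0.00964) than in LSK p53R172H/+ (-0.623). Whether the rise of the ribosomal list goes beyond this short-gene trend was not tested. Mitosis genes rose for 11 of 25 (14, adjusted p = 0.0516; Cdk1 0.64 ± 0.09, Birc5 0.65 ± 0.10) and granulocyte-monocyte genes for 7 of 16 (7, with 1 lower, adjusted p = 0.291; Clec12a 0.90 ± 0.16, Ly86 1.48 ± 0.28). In the same fit the granulocyte-monocyte list had 5 of 16 higher among p53R172H libraries (median 0.76). Among deletion libraries 0 of 16 were higher (median -0.00739). Stem cell genes fell for 8 of 26 (10 adjusted over the list alone, adjusted p = 0.178; Mycn -0.98 ± 0.17, Cdkn1c -1.02 ± 0.21, Hlf -0.66 ± 0.14). The BMP receptor genes Eng (-0.51 ± 0.09) and Acvr2a (-1.21 ± 0.25) fell as 2 of 27 components (2, adjusted p = 0.178). None of these lists held in camera with an estimated correlation. Hspa1b, a heat shock gene, rose by 3.39 ± 0.30 and Hbb-b1 fell by -1.74 ± 0.32.

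The pooled LSK count was 1682 of 16817, 1174 higher and 508 lower. It was 529 in p53R172H libraries and 287 in deletion libraries, or 14 and 36 when each of these sets was fitted alone. DESeq2 gave 2711 and only these groups 1046, and without single libraries the count was 615 (p53+/- 1), 936 (p53+/- 2), 3155 (p53R172H/- 1), 707 (p53R172H/- 2), 1091 (p53R172H/+ 1) and 912 (p53R172H/+ 2). Among deletion libraries alone Trp53 fell by -2.23, Cebpb rose by 3.50 and Ccl3, a chemokine, fell by -1.48. Sex goes with genotype there, with Xist at 273 CPM in p53-/- and 0.148 in p53+/-, Ddx3y at 0 and 26.8 and Eif2s3y at 0 and 39.4, all among the 36 genes. In the pooled fit of the same contrast camera had p53 targets at adjusted p = 0.0466 and cholesterol synthesis at adjusted p = 0.0241 with an estimated correlation. With those libraries fitted alone both were at adjusted p = 0.707 in camera with an estimated correlation. In that fit 0 of 29 p53 targets were called (1 lower adjusted over the list alone) and 1 of 19 cholesterol genes fell (9).

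Leukemic p53R172H/- MEP, compared with p53R172H/- MEP not labelled leukemic, had counts of the BMP ligand genes and less RNA of many myeloid, platelet and stem cell genes. Both groups share the column name prefix, and neither is touched by the label conflict, though they come from separate tables and differ in Y-linked RNA. Ddx3y was at 136 to 171 CPM in the libraries not labelled leukemic and at 0, 58.7 and 0.124 in the leukemic ones. Trp53 was the same within error (0.11 ± 0.23, edgeR adjusted p = 0.776). Bmp2 stood at 7.28 ± 6.85 CPM in leukemic cells and at 0 in the others, at least 78.4-fold higher, and Bmp4 at 10.2 ± 8.69 CPM, at least 110-fold higher, against a floor of 3 counts per library. The 3 leukemic libraries had Bmp2 at 7.34, 0.397 and 14.1 CPM and Bmp4 at 5.92, 20.2 and 4.42 CPM, and without the highest library the folds were at least 41.7 and 55.8. The BMP-induced genes Id1 (3.95 ± 0.68) and Id3 (5.23 ± 1.01) rose with them, as did Gata2, a factor of early progenitors and mast cells (2.10 ± 0.37), while Smad1 (1.21 ± 0.60, edgeR adjusted p = 0.167) did not pass. Klf1 was at -0.60 ± 0.36 (edgeR adjusted p = 0.256) and Gata1 at -0.57 ± 0.19 (edgeR adjusted p = 0.0527), both short of the threshold.

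Granulocyte-monocyte genes fell for 9 of 13 (10 adjusted over the list alone, adjusted p = 0.0539), with Mpo at -6.07 ± 0.60, the protease Prtn3 at -6.49 ± 0.54, Nkg7 at -8.25 ± 0.81 and Ms4a3 at -8.13 ± 0.82. Megakaryocyte genes fell for 12 of 24 and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 0.109), with the factor Fli1 at -7.68 ± 0.74, the platelet chemokine Pf4 at -7.37 ± 0.79, Cd9 at -5.50 ± 0.58 and Selp at -8.76 ± 1.03. Stem cell genes fell for 11 of 21 and 3 rose (12 and 4, adjusted p = 0.0539), Hoxa9 to 0 counts and at least 144-fold lower, Slamf1 at least 73.6-fold, with Hoxa10 at -9.76 ± 1.29 and Prdm16 at -9.56 ± 1.30. Stress and inflammation genes rose: 18 of 19 immediate early genes (19 adjusted over the list alone, adjusted p = 0.274; Klf6 4.48 ± 0.52, Egr1 4.56 ± 0.79) and 11 of 16 NF-kB genes (13, with 1 lower, adjusted p = 0.109; Icam1 5.14 ± 0.46, Nfkbiz 4.78 ± 0.65, Tnfaip3 4.97 ± 0.72). Genes of unfolded protein and amino acid stress rose for 8 of 17 (9, adjusted p = 0.224; Asns 2.42 ± 0.23, Trib3 6.12 ± 0.68, Atf4 1.75 ± 0.20). The STAT5-induced genes Cish (2.41 ± 0.26), Pim1 (2.62 ± 0.35), Socs1 (2.55 ± 0.61) and Socs2 (2.03 ± 0.50) rose, with 2 others of 14 JAK-STAT targets, and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.186).

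Further rises were Tph1, which makes serotonin (at least 924-fold, or 292 without the highest library), the piRNA pathway gene Piwil4 (at least 888-fold), Rgs7 (at least 652-fold) and Hmgcll1 (at least 277-fold). Further falls were St8sia6 (at least 372-fold), Prss50 (at least 368-fold), Runx3 (at least 254-fold) and Acsl6 (at least 238-fold). With an estimated correlation camera kept no list. In edgeR 3333 of 14701 genes changed, 1582 higher and 1751 lower, and the count was 2143 without MEP p53R172H/- 1 and 2081 without MEP p53R172H/- 2.

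**Figure D2:**
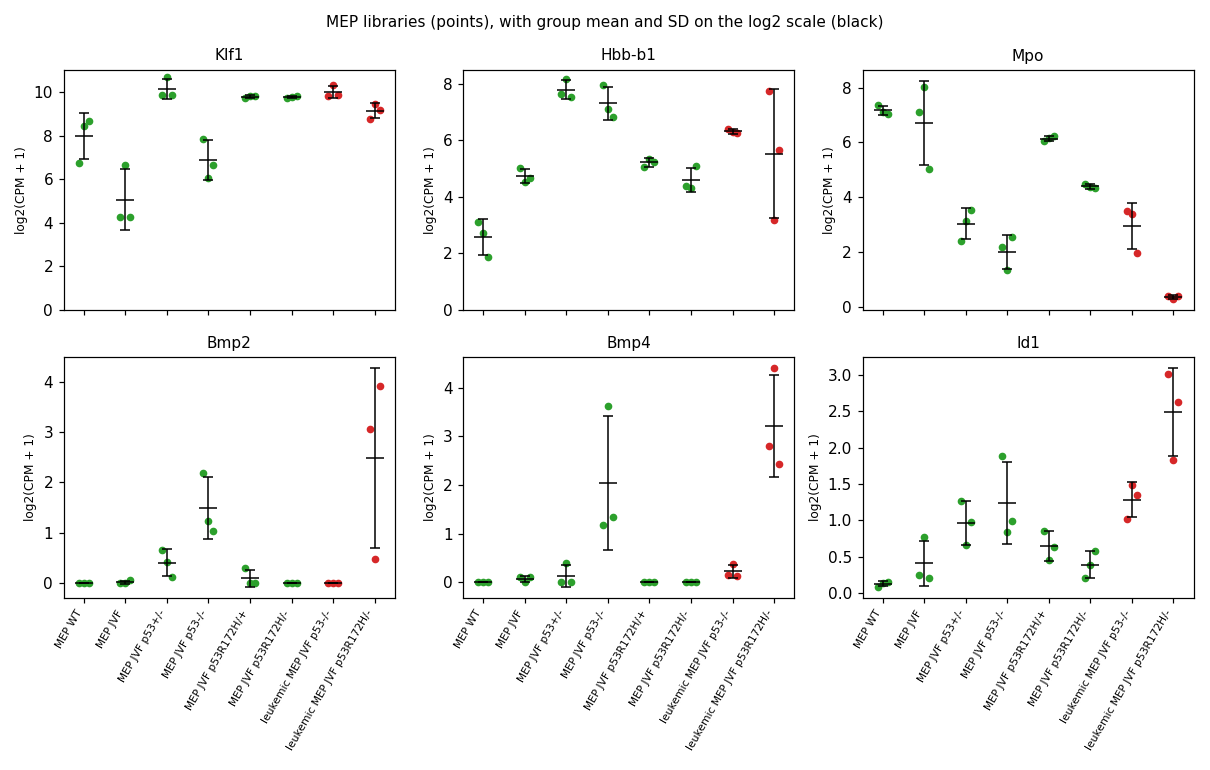
Levels of 6 genes as log2(CPM + 1) (vertical axes) in the MEP groups, with points for libraries (green MEP, red leukemic MEP) and black marks for mean and SD on that scale. Bmp2 and Bmp4 are at 0 CPM in MEP p53R172H/- and at means of 7.28 and 10.2 CPM in leukemic p53R172H/-, and Klf1 is lowest in MEP JVF, at a mean of 45.8 CPM.

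In MEP, red cell genes were lower and those of other lineages higher in JVF than in WT. Trp53 fell by -1.85 ± 0.30. Erythroid maturation genes fell for 19 of 29 and rose for 3 (19 and 4 adjusted over the list alone, adjusted p = 0.383): Trim10 by -2.45 ± 0.35, Rhd by -2.58 ± 0.38, the membrane skeleton genes Epb4.2 (-2.38 ± 0.35) and Spnb1 (-3.81 ± 0.58). Klf1 fell by -2.85 ± 0.61 and Gata1 by -1.20 ± 0.24, although Hbb-b1 rose by 2.14 ± 0.40. Klf1 was at 18.2, 100.9 and 18.3 CPM in JVF 1, 2 and 3 and at 106.8, 351.2 and 412.5 CPM in WT 1, 2 and 3. JVF 2 was thus close to WT 1. Heme genes fell for 8 of 17 (8, with 1 higher, adjusted p = 0.383; Hmbs -1.69 ± 0.23) and DNA replication genes for 15 of 28, with 4 higher (15 and 4, adjusted p = 0.525; Mcm3 -1.50 ± 0.26). Ribosome biogenesis genes fell for 13 of 27, with 3 higher (14 and 3, adjusted p = 0.0849; Polr1b -2.22 ± 0.34). Markers of other cells rose: 5 of 11 dendritic genes (6, adjusted p = 0.383; H2-Aa 4.88 ± 0.46, Cd74 3.83 ± 0.53), and 6 of 15 macrophage genes (6, adjusted p = 0.383; F13a1 3.03 ± 0.34). So did 7 of 16 granulocyte-monocyte genes with 1 lower (8 and 1, adjusted p = 0.383; Ctsg 3.26 ± 0.40) and 5 of 15 mast cell genes (7, adjusted p = 0.383; Il4 4.59 ± 0.47). Lymphoid genes rose for 6 of 12, with 2 lower (7 and 2, adjusted p = 0.383; Sell 3.43 ± 0.44). Pf4 rose (2.93 ± 0.68), and so did 13 of 30 type I interferon genes, with 1 lower (16 and 1, adjusted p = 0.525; Trim30a 1.60 ± 0.30).

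These changes moved with a feature of the JVF MEP libraries. Mitochondrial RNA took 6.47 ± 1.84% of their counts against 0.925 ± 0.312% in WT MEP, and the fifth of genes with the highest GC content lay at -0.985 log2 units from the mean of all libraries, against 0.224 in WT. Sex differed too, with Ddx3y at 162 ± 48.5 CPM in JVF and 0.0379 ± 0.0332 in WT (n = 3 each). JVF 1 (-1.39) and JVF 3 (-1.41) were steepest, and JVF 2 was at -0.156. In edgeR 5722 of 15437 genes changed, 2731 higher and 2991 lower, but 113 with JVF 2 as the lone JVF library, which was then assumed to vary like the other groups. The count was 2984 without JVF 1, 2926 without JVF 3, 3007 without WT 2, 3786 without WT 3 and 3321 in a fit of only these groups. In camera with an estimated correlation no list held. Low Klf1 was not shared by all MEP groups with Jak2 V617F. By group means of TMM-scaled CPM it was at 312 in WT and 43.2 in JVF. The means were 1210 in p53+/-, 880 in p53R172H/- and 820 in p53R172H/+, and 128 in the p53-/- libraries of the MEP table.

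**Figure D3:**
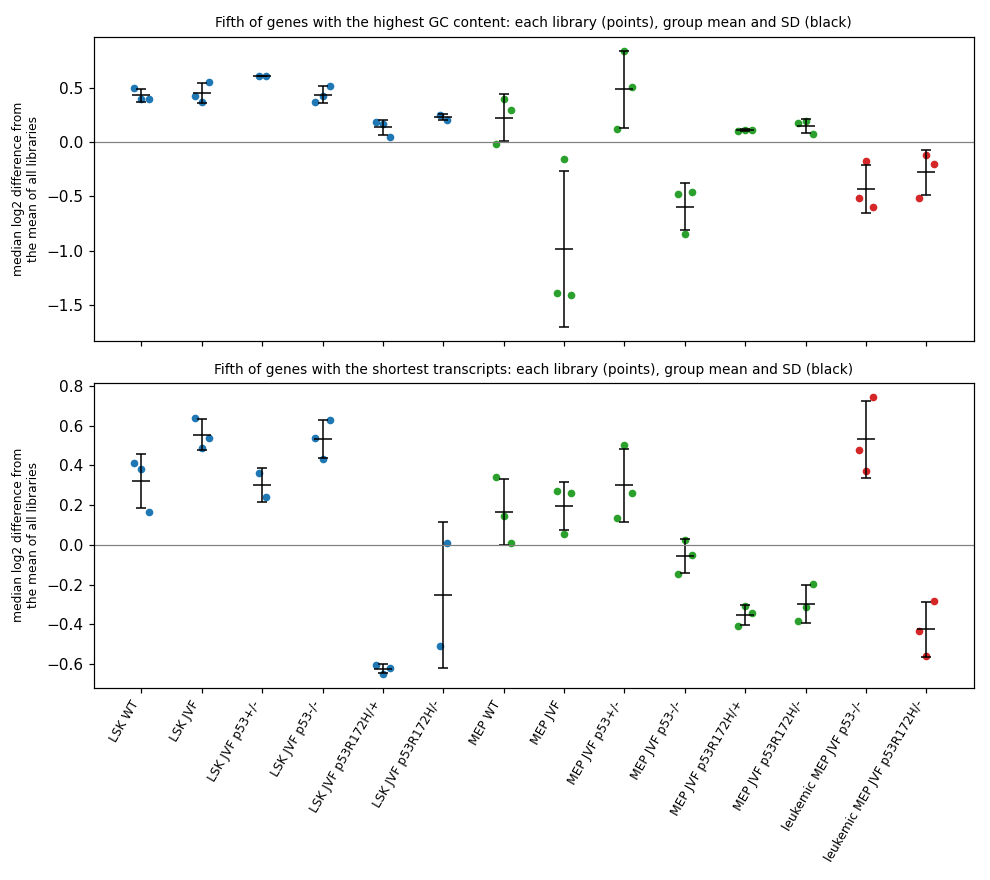
Median log2 difference from the mean of all libraries (vertical axes) for the fifth of genes with the highest GC content (top) and with the shortest transcripts (bottom) in the 14 groups, with points for libraries (blue LSK, green MEP, red leukemic MEP) and black marks for mean and SD. MEP JVF has the lowest mean for high-GC genes, at -0.985, and the p53R172H groups have the lowest means for short genes, from -0.623 in LSK p53R172H/+ to -0.251 in LSK p53R172H/-.

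MEP labelled p53+/- stood apart from JVF in the red cell direction. Trp53 was higher, not lower (0.82 ± 0.30), but was at -0.127 with GC and length curves removed and at -1.02 with WT as the control. Erythroid genes rose for 21 of 29 and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 0.157), led by Hba-a1 (4.44 ± 0.46), Hbb-b2 (2.76 ± 0.29), Epb4.2 (3.40 ± 0.36) and Spnb1 (5.09 ± 0.62). Heme genes rose for 14 of 17, with 2 lower (15 and 2, adjusted p = 0.0909; Hmbs 2.83 ± 0.24, Fech 3.98 ± 0.50). Klf1 rose by 4.81 ± 0.66, from 45.8 ± 47.8 CPM to 1160 ± 408, and Gata1 by 1.11 ± 0.24 (-0.0897 with WT as the control). Cdkn1a, the p53 target that halts the cell cycle, rose by 1.71 ± 0.28 and Mdm2, which degrades p53, by 1.11 ± 0.43. The ligand gene Bmp2 rose by 4.35 ± 1.55, at only 0.582, 0.334 and 0.0901 CPM in the p53+/- libraries. Granulocyte-monocyte genes fell for 13 of 16 (13, adjusted p = 0.0843; Ctsg -6.66 ± 0.47, Clec12a -9.21 ± 0.69) and macrophage genes for 9 of 15 (9, adjusted p = 0.296; F13a1 -10.2 ± 0.52). Mast cell genes fell for 11 of 15 (11, adjusted p = 0.212; Prss34 -6.39 ± 0.88) and megakaryocyte genes for 13 of 27 (13, adjusted p = 0.519), with Pf4 at -4.22 ± 0.72. Cholesterol synthesis genes rose for 12 of 19, with 1 lower (12 and 1, adjusted p = 0.268; Dhcr24 3.92 ± 0.41), and glycolysis genes for 11 of 19 (14, adjusted p = 0.455; Aldoa 2.43 ± 0.35). The erythropoietin-induced hormone gene Fam132b rose by 4.12 ± 0.56 with 6 others of 15 JAK-STAT targets (7, adjusted p = 0.348).

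In edgeR 8099 of 15437 genes changed in this comparison, 3665 higher and 4434 lower, against 2513 with JVF 2 as the lone JVF library, 3864 with only these groups fitted and 2945 with WT as the control. The same mitochondrial share and GC trend of JVF MEP apply. No list held in camera with an estimated correlation.

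Both p53R172H genotypes in MEP were compared with JVF. In p53R172H/- Trp53 was at -0.61 ± 0.30 (edgeR adjusted p = 0.0931) and in p53R172H/+ at 0.12 ± 0.29 (edgeR adjusted p = 0.754), or -1.73 with WT as the control. Klf1 rose by 4.35 ± 0.65 and 4.24 ± 0.65, and the p53 target Cdkn1a fell by -1.12 ± 0.29 and -1.02 ± 0.29. Erythroid genes rose for 17 of 29 in p53R172H/-, with 2 lower (18 and 2 adjusted over the list alone, adjusted p = 0.381; Tspan33 3.71 ± 0.44, Rhag 1.27 ± 0.17), and for 21 in p53R172H/+, with 2 lower (22 and 2, adjusted p = 0.441; Tspan33 3.89 ± 0.44). Heme genes rose for 8 of 17, with 1 lower, and 10 of 17 (9 and 1, and 10 and 1, adjusted p = 0.3 and 0.441; Cpox 4.87 ± 0.44 and 4.84 ± 0.44). Granulocyte-monocyte genes fell for 10 and 8 of 16 (10 and 8, adjusted p = 0.3 and 0.441; Ctsg -5.58 ± 0.45 and -3.90 ± 0.41), and Pf4 by -5.01 ± 0.75 and -5.08 ± 0.76. Type I interferon genes fell for 18 of 30 in p53R172H/-, with 1 higher (20 and 1, adjusted p = 0.514; Xaf1 -3.10 ± 0.49), and for 24 in p53R172H/+, with 1 higher (25 and 1, adjusted p = 0.441; Xaf1 -4.67 ± 0.53). Ccnb1ip1 rose at least 206-fold and at least 257-fold, C2cd4a by 8.57 ± 0.97 and 8.70 ± 0.98, and Kcng2 by 8.55 ± 0.67 and 8.21 ± 0.66. In p53R172H/- neutrophil genes also fell for 8 of 13 (8, adjusted p = 0.381; Lyz2 -4.61 ± 0.58), mast cell genes for 9 of 15 (9, adjusted p = 0.3; Hdc -3.72 ± 0.40) and dendritic genes for 8 of 11 (8, adjusted p = 0.3; H2-Aa -5.23 ± 0.47). Smad7, an inhibitor of BMP and TGF-beta signals, rose by 1.90 ± 0.34.

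These comparisons cannot be told apart from a batch that the column name prefix would mark, and short genes lay low in the p53R172H libraries. Ribosomal protein genes did so too: 24 of 27 fell and 2 rose in p53R172H/- (24 and 2, adjusted p = 0.381; Rpl32 -2.56 ± 0.29), 25 fell and 2 rose in p53R172H/+ (25 and 2, adjusted p = 0.441; Rpl32 -2.71 ± 0.30). In edgeR 8078 genes changed in p53R172H/- (3659 higher, 4419 lower) and 7618 in p53R172H/+ (3591, 4027), or 3550 and 3327 with JVF 2 as the lone JVF library, and 5333 for p53R172H/- with WT as the control. With an estimated correlation camera kept no list.

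Against the libraries labelled p53+/-, MEP p53R172H/+ had Trp53 at -0.70 ± 0.30 (edgeR adjusted p = 0.0815). Jak2 rose by 3.57 ± 0.38, Cdkn1a fell by -2.74 ± 0.30 and Klf1 did not change (-0.56 ± 0.57, edgeR adjusted p = 0.473). Type I interferon genes fell for 18 of 30, with 1 higher (20 and 2 adjusted over the list alone, adjusted p = 0.333; Dhx58 -2.94 ± 0.31, Isg15 -3.08 ± 0.39). Glycolysis genes fell for 14 of 19 (15, adjusted p = 0.333; Bnip3 -2.94 ± 0.36, Pgk1 -2.05 ± 0.29) and ribosomal protein genes for 24 of 27 (27, adjusted p = 0.333; Rps20 -1.71 ± 0.25). Granulocyte-monocyte genes rose for 9 of 16 (11, adjusted p = 0.333; Clec12a 5.10 ± 0.64, Elane 2.19 ± 0.34, Mpo 3.01 ± 0.54), as did F13a1 (7.07 ± 0.49) and Ccnb1ip1 (9.56 ± 0.82). In edgeR 4678 genes changed, 2558 higher and 2120 lower, and 3112 without p53R172H/+ 1, and the column name prefix goes with the genotype here.

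In LSK the 4 comparisons of p53R172H with other genotypes were led by ribosomal protein genes, which fell for 26 of 27 in p53R172H/- against JVF, all 27 in p53R172H/+ against JVF, 26 in p53R172H/- against p53-/- and all 27 in p53R172H/+ against p53+/- (the same counts adjusted over the list alone, adjusted p = 0.267, 0.169, 0.194 and 0.149). In that order Rpl3 was at -1.45 ± 0.09, -1.74 ± 0.08, -1.34 ± 0.09 and -1.47 ± 0.09. Trp53 was at -0.32 ± 0.17 (edgeR adjusted p = 0.14), 0.18 ± 0.15 (edgeR adjusted p = 0.35), 1.78 ± 0.16, where it rose, and 0.06 ± 0.17 (edgeR adjusted p = 0.813). Oxidative phosphorylation genes fell for 20, 22, 21 and 22 of 26, while 1, 2, 1 and 2 rose (21, 22, 21 and 22 lower and 2, 2, 3 and 2 higher adjusted over the list alone, adjusted p = 0.391, 0.211, 0.25 and 0.375). Atp5o fell by -1.61 ± 0.14, -2.12 ± 0.12, -1.56 ± 0.14 and -1.41 ± 0.13. The p53 targets Mdm2 (1.05 ± 0.26, 1.35 ± 0.24, 1.20 ± 0.26 and 1.03 ± 0.27) and Ccng1 (0.55 ± 0.17, 1.07 ± 0.15, 1.20 ± 0.17 and 1.05 ± 0.18) rose in each.

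Macrophage genes fell for 11 of 16 in p53R172H/- against JVF, with 2 higher (11 and 2 adjusted over the list alone, adjusted p = 0.821), Vcam1 at least 1690-fold and Cd5l at least 436-fold, and Id1 (-1.38 ± 0.36) and Id2 (-2.34 ± 0.32) fell there. Smad1 rose by 0.94 ± 0.14 in p53R172H/- against JVF, where Klf1 fell by -1.08 ± 0.39, and Klf1 fell by -1.81 ± 0.34 in p53R172H/+. With WT as the control Id1 (0.446) and Klf1 (0.528) had the opposite sign in p53R172H/- and neither was called. Stem cell genes rose for 15 of 26 in p53R172H/+ against JVF, with 3 lower (15 and 3, adjusted p = 0.944; Mycn 1.68 ± 0.22, Angpt1 1.24 ± 0.17). Homologous recombination genes rose for 11 of 16 in p53R172H/- against p53-/-, with 1 lower (13 and 1, adjusted p = 0.589; Exo1 1.20 ± 0.21, Brca2 0.84 ± 0.16). Cholesterol genes rose for 10 of 19 in the latter comparison, with 2 lower (10 and 2, adjusted p = 0.25; Sqle 1.33 ± 0.12, Ldlr 1.14 ± 0.18). In p53R172H/+ against p53+/- granulocyte-monocyte genes fell for 11 of 16, with 1 higher (11 and 1, adjusted p = 0.99; Prtn3 -1.58 ± 0.16), and Bmp4 was at least 14.2-fold higher, at 1.34 ± 0.153 CPM.

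A batch that the column name prefix would mark cannot be told apart from genotype in these 4 comparisons, and sex goes with genotype in each but the last. None of the lists named for them held in camera with an estimated correlation. The edgeR counts were 6353 (3459 higher, 2894 lower), 8065 (4242, 3823), 5564 (3024, 2540) and 6133 (2879, 3254) of 16817. Without p53R172H/- 1 the first was 4128 and the third 3262, without p53+/- 1 the fourth was 3719, and fits of only the groups compared gave 3959 for the first and 3016 for the third.

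The p53-/- MEP were compared with JVF in both readings of the labels. With the libraries of the MEP table, Trp53 fell by -3.76 ± 0.33, and with those of the leukemic table by -2.30. The readings went opposite ways for Cdkn1a (3.09 ± 0.30 and -1.74) and the same way for Klf1 (1.57 ± 0.58 and 4.81), Id1 (2.09 ± 0.69 and 2.35). Granulocyte-monocyte genes fell for 13 of 16 in the first, with 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.07; Nkg7 -9.19 ± 0.55, Ctsg -6.15 ± 0.46), and for 11 of 16 in the second (11, adjusted p = 0.199). In the first reading the ligands Bmp2 (6.87 ± 1.55, 1.99 ± 1.38 CPM) and Bmp4 (6.35 ± 1.60, 4.73 ± 5.79 CPM) rose. Bmp4 was at 1.25, 11.4 and 1.53 CPM in the 3 libraries (log2 change 4.79 without the second) and was not called by DESeq2 (adjusted p = 0.112). With JVF 2 as the lone JVF library neither ligand was called (edgeR adjusted p = 0.0586 for Bmp2 and 0.0855 for Bmp4). In the second reading Bmp2 was at 0 in each p53-/- library and Bmp4 at 0.114, 0.299 and 0.0964 CPM. The values that follow in this paragraph are again of the first reading. Glycolysis genes rose for 11 of 19, with 1 lower (12 and 1, adjusted p = 0.4; Bnip3 4.12 ± 0.38, Pgk1 2.63 ± 0.30). Stem cell genes fell for 17 of 23, with 3 higher (17 and 3, adjusted p = 0.314; Meis1 -9.34 ± 0.78), Hoxa9 at least 87.5-fold and Tek at least 267-fold. Tph1 (12.1 ± 1.04), the costimulator Tnfrsf9 (10.1 ± 0.82) and the eye and brain factor Pax6 (9.55 ± 0.68) rose. Mast cell protease Cma1 rose too (9.25 ± 1.18), to 206 ± 140 CPM, while the mast cell gene Cpa3 was at 5.47 ± 3.77 CPM.

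The first reading called 6715 genes in edgeR, 2955 higher and 3760 lower, and 3841 with JVF 2 as the lone JVF library, and the second 6484 (3317 higher, 3167 lower). In the second reading Bnip3 (-1.35), Pgk1 (-0.625), Tnfrsf9 (-0.579) and Hoxa9 (0.89) had the opposite sign, and with WT as the control so did Klf1 (-1.28). Glycolysis genes then fell for 6 of 19, with 2 higher (6 and 2; camera adjusted p = 0.164, or 0.722 with an estimated correlation). Mitochondrial RNA was at 1.06 ± 0.27% of counts in the first p53-/- set, 6.4 ± 0.291% in the second and 6.47 ± 1.84% in JVF, and sex goes with genotype in the second reading.

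Between p53R172H/- and p53-/- MEP, with the libraries of the MEP table as p53-/-, Trp53 was higher by 3.15 ± 0.32 in p53R172H/- and Cdkn1a lower by -4.21 ± 0.32. Ribosome biogenesis genes were higher for 21 of 27 (22 adjusted over the list alone; Rrs1 5.81 ± 0.45, Srm 4.72 ± 0.45), a list that held in camera with an estimated correlation (adjusted p = 0.0246). DNA replication genes were higher for 24 of 28 (24; Ccne1 6.70 ± 0.50, adjusted p = 0.577 with an estimated correlation). Mast cell genes were lower for 7 of 15, with 2 higher (7 and 3; Hdc -8.13 ± 0.47, adjusted p = 0.577 with an estimated correlation in camera), and Tph1 at least 3310-fold. With the libraries of the leukemic table instead, Trp53 was higher by 1.97, Cdkn1a by 0.91 (edgeR adjusted p = 0.0585), and ribosomal protein genes fell for 27 of 27 (camera adjusted p = 0.245 with an estimated correlation). In that reading ribosome biogenesis genes were higher for 8 of 27, with 2 lower (8 and 2), with camera at adjusted p = 0.642, or adjusted p = 0.99 with an estimated correlation. Srm was at -0.139 and Hdc at 1.16, opposite in sign to the reading by table. DNA replication genes were higher for 11 of 28 there, with 6 lower (13 and 6; camera adjusted p = 0.312, or 0.99 with an estimated correlation), and 0 of 14 mast cell genes were called (0). Sex goes with genotype in that reading. The counts were 8694 (4486 higher, 4208 lower) and 5179 (3510, 1669), both with the column name prefix alongside the genotype.

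For MEP with both copies altered against 1 copy altered, Trp53 fell by -2.66 ± 0.22 in the pooled fit. DNA replication genes fell for 22 of 28 (22, with 1 higher, adjusted over the list alone, adjusted p = 0.431; Ccne1 -2.70 ± 0.29). Heme genes fell for 11 of 17, with 3 higher (12 and 3, adjusted p = 0.458; Uros -1.30 ± 0.17). Erythroid genes fell for 15 of 29, with 3 higher (15 and 3, adjusted p = 0.544; Hemgn -1.63 ± 0.16, Rhd -2.37 ± 0.27), with Klf1 at -1.57 ± 0.41 and Gata1 at -0.82 ± 0.17. The edgeR count was 5105, 2174 higher and 2931 lower, but it was 8130 in deletion libraries and 7 in p53R172H libraries (6376 and 1107 when fitted alone). In p53R172H libraries fitted alone DNA replication genes rose for 7 of 28 (9, with 1 lower), with camera at adjusted p = 0.00507, or 0.405 with an estimated correlation. In the p53R172H libraries of the pooled fit Ccne1 (0.097), Klf1 (0.102), Gata1 (0.185) and Cdkn1a (-0.0942) had the opposite sign. The pooled result rests on the deletion libraries, with the label conflict and the p53+/- label in it. With p53-/- by column name it was 3557, where Cdkn1a was at -1.86 against 0.64 ± 0.20 and Klf1 at -0.03 (edgeR adjusted p = 0.969). By column name Ccne1 was at 0.504, and DNA replication genes fell for 9 of 28, with 1 higher (9 and 2; camera adjusted p = 0.262, or 0.779 with an estimated correlation). Heme genes fell for 5 of 17 there, with 1 higher (5 and 1; camera adjusted p = 0.192, or 0.757 with an estimated correlation).

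Among leukemic libraries, p53R172H/- were compared with p53-/- of the leukemic table. Trp53 was higher by 1.79 ± 0.29. Bmp2 was at least 60.8-fold higher (32.3 without the highest library), Bmp4 higher by 5.67 ± 0.84 (4.71 without p53R172H/- 2, which had 20.2 CPM against 5.92 and 4.42), and the receptor-regulated Smad1 (3.26 ± 0.81), Smad9 (3.95 ± 0.80) and the BMP modulator Twsg1 (1.33 ± 0.26) rose among 8 of 18 BMP components (9 adjusted over the list alone, adjusted p = 0.515). Gata2 was higher by 4.24 ± 0.41 and Klf1 lower by -1.09 ± 0.25. Granulocyte-monocyte genes fell for 8 of 12 (8, adjusted p = 0.451; Prtn3 -7.45 ± 0.69, Mpo -4.89 ± 0.65), with Pf4 at -7.39 ± 0.99. Immediate early genes rose for 14 of 19, with 1 lower (16 and 1, adjusted p = 0.566; Klf6 4.72 ± 0.64). NF-kB genes rose for 8 of 16 (9, adjusted p = 0.46; Icam1 4.77 ± 0.51) and unfolded protein stress genes for 9 of 16 (10 and 1, adjusted p = 0.52; Trib3 6.79 ± 0.80). Ribosomal protein genes fell for 26 of 27 (26, adjusted p = 0.451; Rps24 -2.46 ± 0.20) and oxidative phosphorylation genes for 18 of 26 (19, adjusted p = 0.515), with mitochondrial RNA at 0.711 ± 0.254% of counts against 6.4 ± 0.291% in p53-/-.

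The column name prefix, genotype, Xist and this mitochondrial share go together in the leukemic pair. No list held in camera with an estimated correlation. In edgeR 4596 of 12897 genes differed, 2321 higher and 2275 lower, and 2718 without p53-/- 1. With the libraries of the MEP table as leukemic p53-/-, the count was 6837 (3556, 3281), Smad1 was at 2.07 and Cdkn1a at -4.34. In contrast, Bmp2 (1.98, edgeR adjusted p = 0.165), Bmp4 (1.19, edgeR adjusted p = 0.326) and Klf1 (2.18, where it was higher) differed from the first reading. NF-kB genes then rose for 5 of 15 and 3 fell (5 and 3; camera adjusted p = 0.863, or 0.948 with an estimated correlation), with Icam1 at -0.113. Camera also lost BMP components at the preset correlation (9 of 20 higher, 2 lower; preset adjusted p = 0.289), oxidative phosphorylation (3 of 26 higher, 11 lower; preset adjusted p = 0.203), immediate early genes (11 of 18 higher, 1 lower; preset adjusted p = 0.0567) and unfolded protein stress genes (9 of 16 higher, 1 lower; preset adjusted p = 0.0854).

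The leukemic against the other p53-/- MEP libraries differed at 8103 of 14701 genes (4227 higher, 3876 lower), a comparison whose sign rests on the label reading and is the mirror image in the other. Mitochondrial RNA took 6.4 ± 0.291% of counts in the leukemic table and 1.06 ± 0.27% in the other, and sex goes with the tables. As read by table, Trp53 was higher by 1.36 ± 0.23 in the leukemic table, Cdkn1a lower by -4.94 ± 0.67 and Klf1 higher by 3.16 ± 0.39. Ribosome biogenesis genes were higher for 20 of 27 (21 adjusted over the list alone; Odc1 4.73 ± 0.24) and glycolysis genes lower for 15 of 18 (15; Pkm2 -6.85 ± 0.51), with camera adjusted p = 0.0522 and 0.474 with an estimated correlation. Bmp2 was at least 16.7-fold lower, or 10 without the highest library.

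The leukemic change differed between p53R172H/- and p53-/- at 7317 of 14701 genes (3370 higher, 3947 lower). Trp53 differed by -1.25 ± 0.33, Klf1 by -3.76 ± 0.53, Id1 by 3.78 ± 0.89 and Gata2 by 4.56 ± 0.53. Granulocyte-monocyte genes were lower for 10 of 13, with 1 higher (10 and 1 adjusted over the list alone; Prtn3 -8.52 ± 0.68). NF-kB genes were higher for 12 of 16 (12; Icam1 10.1 ± 0.65), with camera adjusted p = 0.249 and 0.187 with an estimated correlation. By column name 6148 genes differed, with Id1 at 4.12, while Klf1 (2.55), Trp53 (1.46) and Gata2 (-0.36) had the opposite sign. NF-kB genes were then higher for 3 of 16, with 2 lower (5 and 2; camera adjusted p = 0.815, or 0.964 with an estimated correlation), and Icam1 was at 0.15 (edgeR adjusted p = 0.858). Prtn3 was at -4.47, with granulocyte-monocyte genes lower for 8 of 13 (9, adjusted p = 0.36).

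The p53-/- change against JVF differed between MEP and LSK at 5714 of 17928 genes (2263 higher, 3451 lower in MEP). Trp53 differed by -1.65 ± 0.36, Hbb-b1 by 3.95 ± 0.59 and Mpo by -5.42 ± 0.63. Granulocyte-monocyte genes were lower in MEP for 13 of 16, with 2 higher (13 and 2 adjusted over the list alone; Nkg7 -9.41 ± 0.51, Ctsg -6.67 ± 0.49), which held in camera with an estimated correlation (adjusted p = 0.0144). Stem cell genes were lower for 18 of 26, with 2 higher (18 and 2; Meis1 -9.31 ± 0.68, adjusted p = 0.0958 with an estimated correlation). By column name the count was 5689, with Trp53 at -0.32 (edgeR adjusted p = 0.571). Granulocyte-monocyte genes were then lower for 11 of 16, with 1 higher (12 and 1; camera adjusted p = 6.33e-08, or 0.0833 with an estimated correlation). The JVF MEP libraries, with mitochondrial RNA at 6.47 ± 1.84% of counts against 1.06 ± 0.27% in p53-/- MEP, the GC trend described above and 7 of 16 granulocyte-monocyte genes above WT, enter this difference.

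The Jak2 V617F change itself differed between MEP and LSK at 4170 of 17928 genes (1710 higher, 2460 lower in MEP). Trp53 differed by -1.79 ± 0.36. Erythroid genes were lower in MEP for 19 of 29 (24 adjusted over the list alone, adjusted p = 0.0836; Add2 -4.49 ± 0.65, Rhag -2.70 ± 0.41). Heme genes were lower for 11 of 17 (12, adjusted p = 0.0836; Hmbs -2.65 ± 0.30), with Klf1 at -4.53 ± 0.76 and Gata1 at -1.85 ± 0.32. Lymphoid genes were higher for 7 of 14, with 1 lower (7 and 3, adjusted p = 0.0836; Sell 3.53 ± 0.44). None of these lists held in camera with an estimated correlation, and the JVF MEP features above enter this difference.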

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

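Most tests below were written before their values were seen, except the exchange test of the p53-/- sets and the test of the granulocyte-monocyte gate, which were chosen after seeing the data. A test of the difference itself picked out 3 differences between changes. The leukemic change differed between p53R172H/- and p53-/- at 7317 genes in edgeR, including Trp53 (-1.25), Id1 (3.78), Klf1 (-3.76), Gata2 (4.56), Prtn3 (-8.52) and Icam1 (10.1). With the p53-/- libraries grouped by column name these were at 1.46, 4.12, 2.55, -0.36, -4.47 and 0.15, so Trp53, Klf1 and Gata2 turn and Gata2 and Icam1 lose their call. The p53-/- change differed between MEP and LSK at 5714 genes, including Trp53 (-1.65), Hbb-b1 (3.95), Mpo (-5.42), Meis1 (-9.31), Nkg7 (-9.41) and Ctsg (-6.67), which by column name were at -0.32 (not called), 3.06, -4.09, -4.67, -3.63 and -5.08. The Jak2 V617F change differed between MEP and LSK at 4170 genes, including Trp53 (-1.79), Klf1 (-4.53), Gata1 (-1.85), Add2 (-4.49), Rhag (-2.70), Hmbs (-2.65) and Sell (3.53).

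The p53-/- MEP libraries of the 2 tables raise the question of an exchange between the groups. Across 14701 genes, the change from the MEP-table to the leukemic-table p53-/- libraries ran against the leukemic change of p53R172H/- (Pearson r = -0.28, Spearman -0.21), and of 2080 genes called in both, 1461 (70.2%) went opposite ways, as an exchange predicts. Chromosome medians pointed the same way: their SD over autosomes was 0.208 to 0.221 in the MEP-table libraries and 0.0758 to 0.0957 in the leukemic-table ones, a gap of 0.11 between the closest libraries, against 0.304 to 0.311 in leukemic and 0.0682 to 0.0832 in other p53R172H/- MEP, so this test too fits an exchange. Mast cells or basophils as the source of Hdc (328 CPM) in the MEP-table libraries predicted Cpa3, Fcer1a and Ms4a2 at least 2-fold above p53R172H/- MEP. Cpa3 was at 0.959 of that level (Fcer1a 1.16, Ms4a2 25.2), which does not meet that prediction. Fitted alone against p53+/-, 7 of 12 mast cell genes were higher in these libraries and 0 lower. Such a source is therefore not excluded. A biological difference between leukemic p53 genotypes also gives opposite changes, and chromosome medians of RNA do not measure leukemia itself, so the labels stay unresolved, and the assignment by table was kept.

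The large counts of p53-altered MEP against JVF MEP lean on JVF libraries with a GC trend and a high mitochondrial share. Removal of a GC curve left 7514 genes called for p53+/- against JVF, and removal of a length curve 8310, against 8099 without, so neither curve is the whole cause. Granulocyte-monocyte progenitors in the JVF gate predicted Mpo, Elane and Prtn3 at least 2-fold above WT. Elane was at 0.365 of WT (Mpo 0.986, Prtn3 2.87), which does not meet that prediction. These ratios carry no correction for the GC trend of the JVF libraries. Of the 16 genes of the list 7 rose against WT, such as Ctsg (9.58-fold) and Ms4a3 (4.97-fold), and 1 fell. Such cells in the gate are therefore not excluded. With JVF 1 and 3 left out 2513 genes were called, and a smaller sample alone lowers a count, so a library artifact in those 2 is still open beside the Trp53 genotype.

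Ribosomal protein genes fell in the p53R172H libraries. In LSK p53R172H/+ against p53+/- their median of -2.01 lay at percentile 0 of 10000 lists matched on length and mean expression (median -0.96, 5th percentile -1.19). Lengths were those of each gene's longest annotated transcript, which can be longer than the RNA present. The matched lists also take no account of the correlation between members of this list, estimated at 0.63 for the same contrast in MEP. Loss of short transcripts is therefore not excluded. Removal of a GC curve left -1.81, and removal of a length curve -1.17. The same contrast in LSK and MEP had r = 0.35 over 14784 genes, which both a batch and a genotype effect predict, so a batch cannot be excluded.

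Other groupings of the same libraries were tried for the 16 comparisons with at least 3 libraries on each side, not for the 4 LSK comparisons that involve groups of 2 or the 3 differences between changes. With 3 libraries on each side there are 10 splits, too few for a share under 0.05. The real grouping was the 1 split with the highest count in each of these cases, and the highest other count was 2759 for MEP JVF against WT, 1091 for MEP p53-/- against JVF and 970 for MEP p53+/- against JVF. It was 1 for LSK JVF against WT and for WT LSK against MEP. It was 0 for MEP p53R172H/- against JVF and against p53-/-, MEP p53R172H/+ against JVF and against p53+/-, LSK p53-/- and LSK p53R172H/+ against JVF, and the 3 leukemic comparisons. For both copies altered against 1 copy altered, 4 of 100 splits in MEP called at least the real 5105 genes, up to 5970, and 3 of the 4 kept the deletion groups apart. In LSK 1 of 100 splits did so, the real one, and the highest other called 253.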

How the results depend on the processing

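The values here come from edgeR except where DESeq2 is named, and gene results were recomputed only for the genes the text names. Settings with WT as control, JVF 2 alone, libraries with or without the column name prefix, libraries fitted alone, the fit without p53-/-, GC and length curves removed and p53-/- by column name were added after seeing the data. For 337 named gene results, 4578 of 4935 recomputed values kept direction and side of the threshold, 295 lost the threshold, 18 gained it and 44 reversed. The cause was not tested unless fewer libraries or genes are part of the setting. At depths of 14.9 to 57.1 in units of 1e6, 3 counts correspond to 0.202 and 0.0526 CPM. The lowest Bmp2 level in MEP p53+/-, 0.0901 CPM, is such a count. In leukemic p53R172H/- Bmp2 (0.397 to 14.1 CPM) and Bmp4 (4.42 to 20.2 CPM) lay above that floor, and varied between the libraries.

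Counts moved over 1.5-fold as follows. LSK JVF against WT (718): DESeq2 1594. LSK p53-/- against JVF (145): DESeq2 554, no filter 288, GC and length curves removed 233, only these groups 77, WT as control 456. LSK p53+/- against JVF (214): DESeq2 1454, no filter 389, curves removed 138, only these groups 532, WT as control 88. LSK both copies against 1 copy (1682): DESeq2 2711, only these groups 1046, deletion libraries 287 or 36 alone, p53R172H libraries 529 or 14 alone. Only these groups gave 3959 for LSK p53R172H/- against JVF (6353), 3016 for it against p53-/- (5564), 3321 for MEP JVF against WT (5722) and 3864 for MEP p53+/- against JVF (8099). WT as control gave 2945 for MEP p53+/- (8099) and 5333 for MEP p53R172H/- (8078). MEP both copies against 1 copy (5105) gave 8130 in deletion libraries and 7 in p53R172H libraries, or 1107 alone. With p53-/- by column name MEP p53R172H/- against p53-/- gave 5179 (8694). With JVF 2 as the lone JVF library, assumed to vary like the other groups, counts were 113 (MEP JVF against WT), 3841 (p53-/-), 3550 (p53R172H/-), 2513 (p53+/-) and 3327 (p53R172H/+).

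Another scaling moved the share of higher calls for LSK JVF against WT from 437 of 718 to 535 of 750 with RLE factors. For LSK p53-/- against JVF DESeq2 had 320 higher and 234 lower (102 and 43 in edgeR). For LSK p53+/- against JVF DESeq2 had 555 and 899 and RLE 97 and 97 (145 and 69). The median log2 change moved with RLE from 0.174 to 0.295 for WT LSK against MEP and from 0.101 to 0.218 for the Jak2 difference between MEP and LSK.

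Leaving out each library in turn gave these ranges. LSK: JVF against WT 179 to 495, p53-/- 51 to 161, p53+/- 11 to 152, p53R172H/- 4128 to 6576, p53R172H/+ 6951 to 7355, p53R172H/- against p53-/- 3262 to 6017, p53R172H/+ against p53+/- 3719 to 5230, both copies against 1 copy 615 to 3155. MEP, in the same order: 2926 to 6975, 5408 to 7645, 6070 to 8797, 6147 to 8951, 5703 to 8449, 7550 to 8023, 3112 to 5809 and 4123 to 6142. Leukemic p53R172H/- against p53-/- 2718 to 5279, leukemic against not leukemic p53R172H/- 2081 to 4291 and p53-/- 7010 to 7917. WT LSK against MEP 8302 to 8633. The differences of changes: p53 genotypes 6523 to 7772, p53-/- by cell 4877 to 6926, Jak2 by cell 2797 to 5757.

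The replicate block gave 470 for LSK JVF against WT (718) and 85 for LSK p53+/- against JVF (214), and no other count moved over 1.5-fold. Same-numbered libraries mostly did not deviate together (correlations from -0.11 to 0.27 in MEP, -0.082 to 0.082 in LSK and 0.0045 to 0.14 in leukemic MEP). The correlation was over 0.1 in 7 of 30 MEP pairs, 0 of 36 LSK pairs and 1 of 3 leukemic pairs. The numbers were therefore not taken to pair the samples.

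Genes reversed with p53-/- by column name. MEP p53-/- against JVF: Bnip3 -1.35, Pgk1 -0.625, Tnfrsf9 -0.579, Hoxa9 0.89, Cdkn1a -1.74. MEP p53R172H/- against p53-/-: Cdkn1a 0.914, Hdc 1.16, Srm -0.139. MEP both copies: Ccne1 0.504 (0.906 in deletion libraries), Cdkn1a -1.86 (-3.64). Leukemic p53R172H/- against p53-/-: Icam1 -0.113, Klf1 2.18. Leukemic against not leukemic p53-/-, a mirror by construction: Bmp2 8.86, Cdkn1a 4.94, Klf1 -3.16, Odc1 -4.73, Pkm2 6.85, Trp53 -1.36. Its difference from p53R172H/-: Gata2 -0.36, Klf1 2.55, Trp53 1.46.

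Genes reversed in p53R172H libraries for MEP both copies: Ccne1 0.097 (0.0578 alone), Cdkn1a -0.0942 (-0.134), Gata1 0.185 (0.146), Klf1 0.102 (0.0628). Genes reversed with WT as control: LSK p53+/- Birc5 0.0206 and Ccnb1 0.477; LSK p53-/- Satb1 -0.0698, Cd86 0.295 and Pcna-ps2 0.0868; LSK p53R172H/- Id1 0.446 and Klf1 0.528; LSK p53R172H/+ Id1 0.443; MEP p53+/- Gata1 -0.0897 and Trp53 -1.02; MEP p53-/- Klf1 -1.28; MEP p53R172H/+ Trp53 -1.73. Trp53 in MEP p53+/- against JVF was -0.127 with GC and length curves removed.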

Other observations

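The genes of this part were chosen after seeing the data. Pax6, a factor of eye and brain development, was at 62.4 ± 12.2 CPM in leukemic p53R172H/- MEP and 115 ± 16.5 in the p53-/- libraries of the MEP table (n = 3 each), and at 0.15 ± 0.149 in the p53-/- libraries of the leukemic table and 0.143 ± 0.152 in MEP JVF (n = 3 each).

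Sex-linked genes differed between groups. Xist, expressed from the inactive X chromosome of female cells, was at 272 ± 76.1 CPM in MEP WT, 295 ± 123 in the p53-/- libraries of the leukemic table, 456 ± 100 in LSK WT, 262 ± 30.6 in LSK JVF and 267 ± 24.6 in LSK p53-/- (n = 3 each). It was at 0.781 ± 0.531 in MEP JVF, 4.78 ± 4.33 in the p53-/- libraries of the MEP table and 0.388 ± 0.671 in leukemic p53R172H/- (n = 3 each). The Y chromosome gene Ddx3y was at 162 ± 48.5 CPM in MEP JVF and 224 ± 164 in the p53-/- libraries of the MEP table (n = 3 each), and at 0, 58.7 and 0.124 in the 3 leukemic p53R172H/- libraries. Sex therefore goes with genotype in the comparisons of MEP JVF with WT, of LSK p53+/- and p53R172H with JVF, of LSK p53-/- with p53+/- and p53R172H/-, and of the 2 p53-/- sets. It is also part of the LSK comparison of both with 1 altered copy, and Xist differs in the leukemic pair. By column name it goes with p53-/- MEP against JVF, p53+/- and p53R172H/-, and with WT as the control it goes with each MEP genotype of the MEP table and with LSK p53+/- and p53R172H. Ddx3y also differs between leukemic and other p53R172H/- MEP, the latter at 155 ± 17.8 CPM (n = 3).

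Chromosome medians in leukemic p53R172H/- MEP, from expression with the GC trend removed, were high on chromosome 15 (0.54, 0.433 and 0.576 in the 3 libraries) and low on chromosome 12 (-0.571, -0.198 and -0.475). In the second library the extremes were chromosome 8 (0.511) and chromosome 7 (-0.622). In the p53-/- libraries of the MEP table chromosome 10 was low in each library (-0.575, -0.68 and -0.617), and so was chromosome 4 (-0.478, -0.383 and -0.498).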
